A study of Mus musculus with 6 samples.

How the data were processed

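B/CMBA.Ov cells were seeded in plates a day before transfection and given either a miR-15a-3p mimic or a negative control mimic at 20 nM by a lipid reagent, per the labels' protocols. Total RNA was taken 48 h later, amplified with a whole-transcript kit, labelled with biotin and hybridised to a mouse gene array, 3 arrays for each mimic. The groups and replicate numbers come from the sample titles.

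The per-array values were log2 values of 35556 transcript clusters, already summarised and normalized by the authors. The submitters' processing notes name RMA, MAS5, Affymetrix Expression Console and Partek, with no version, role or order, and the gene annotation build is not given in the sources used here. The log2 scale was read from the range of the deposited values, from 2.73 to 13.91. No detection call came with them, so values near background could not be set apart. A second file, the authors' deposited table, compares the mimic with the control over 241419 exon-level probe sets. It gives an unadjusted p-value, a linear ratio and further scores, per the file headers: a signed fold change, an F statistic and sums of squares. A further file holds a subset of it with a deposited p-value and signed fold. Tested on the files, that subset is exactly the 1768 probe sets with p under 0.05 and a signed fold of -2 or lower.

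The sums of squares and F values of the authors' deposited table correspond to an analysis of variance with 2 model and 3 error degrees of freedom. The variance of its contrast is 0.833 times the error variance, which is what a comparison of 2 with 3 arrays gives, where 3 with 3 would give 0.667. Its ratios correlated best, across genes, with those of the per-array values when mimic replicate 1 was left out (r = 0.948, against 0.936 with all 6 arrays). Genes are not independent replicates, and which arrays entered is an inference from the values. All tests below used all 6 arrays.

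The file of per-array values names no genes. A transcript cluster was named from the exon-level probe sets of the authors' deposited table whose IDs lie between its own ID and the next cluster ID. This was checked over the 17009 clusters with at least 4 such probe sets. The fold changes of both tables correlated with r = 0.936 with the cluster's own interval and with r = 0.0955 and 0.0968 with the next and the previous one. All 114 clusters with a log2 change over 1 in size had the same sign in both tables. Symbols were updated through RefSeq accessions, symbols and synonyms of the RefSeq gene table of assembly GRCm38.p6, used for names and gene order alone. Exactly 1 symbol was found for 24149 clusters, several for 800 and none for 10607. Of the single symbols, 20505 came by accession, 2311 by symbol and 532 by synonym, and 801 were kept as in the file. Where a gene had several clusters (1703 genes), the one with the highest mean log2 value was used, which left 21156 genes. No position is given, as the build behind the array annotation is not given in the sources used here.

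The comparison was a limma fit (lmFit and eBayes, limma 3.58.1, R 4.3.3) of the log2 values as deposited, with no filter and no block, and two-sided tests with Benjamini-Hochberg adjustment over all genes at 0.05. Fold changes are mimic over control. Gene lists (24, with 576 distinct genes, of which 7 stand on more than 1 list) were written before the data were examined, as were the tests, their alternatives and the rule for naming genes. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 24 lists, and beside it with an estimated correlation and with fry. The rule for named genes took, among genes past the threshold whose groups did not overlap, the 12 largest rises and the 12 largest falls, leaving out symbols of the Gm, RIKEN, LOC and receptor gene cluster type. It added up to 4 members of each list with the smallest adjusted p, Dleu2, Mir15a, Mir16-1, Ago2 and Dicer1. List members named beyond this rule, to spell out small counts, were chosen after their values were seen. Some genes that the rule or a small count would name are not reported here. The overlap with the authors' deposited list used Fisher's exact test. The code was tested on simulated data of 21156 genes, with 200 genes outside the lists changed and the 25 sterol genes shifted by a log2 of -0.3. Of 100 genes changed by a log2 of 0.5, 99% were recovered, of 100 changed by a log2 of 1, 100%, and 13 of the 25 sterol genes were called. Of all 222 calls, 10 were false, and camera called the shifted list and 0 of the other 23. The simulated genes varied independently of each other, while the estimated correlation within the real lists reached 0.507, in the G2/M list. The simulation therefore cannot show how often camera calls a list falsely when its genes vary together.

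The alternatives were filters on dim genes (mean log2 at or above 6, or at or above the median of 7.27), quantile normalization, median centring, the replicate number as a block, each array left out in turn, a trended and robust prior, array weights, other ways of handling several clusters of a gene, and other thresholds. A test of genes with a site for the microRNA seed was planned and not run, because 3′ UTR sequences were not used here. The authors' deposited table was not used as a source of values, since it holds ratios and not values per array. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.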

Results

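RNA from B/CMBA.Ov cells, a mouse line derived from the ovary of the BALB/c strain, was measured on 6 whole-transcript expression arrays 48 h after transfection with a synthetic small RNA. On 3 of the arrays the cells had received a mimic of miR-15a-3p, the microRNA cut from the 3′ arm of the miR-15a precursor, and on the other 3 they had received a negative control mimic, each at a final concentration of 20 nM. The comparison asks which transcripts differ between cells given this microRNA mimic and cells given the control. Each array gave a log2 value for 35556 transcript clusters, with array medians between 6.94 and 7.01, and 21156 named genes were tested. Across clusters, arrays of the same group correlated with r from 0.996 to 0.998, and arrays of different groups with r from 0.992 to 0.994. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these arrays, which may be technical, and the number of arrays limits the precision.

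The transcriptome of the cells given the miR-15a-3p mimic differed widely from that of the control cells, mostly by small amounts. At a limma adjusted p under 0.05, 1286 genes rose and 1194 fell, 2480 in all, and the median size of their log2 fold change was 0.38. A change of at least 2-fold was reached by 24 of the risen and 26 of the fallen genes. Enpp2, which encodes autotaxin, the secreted enzyme that makes lysophosphatidic acid, rose the most of the genes tested, 7.33-fold. Ifit1, an interferon-induced gene, fell the most, to a ratio of 0.296. In 29.6% of the genes the 3 values of one group all lay above the 3 of the other, against 10% by chance. The count of changed genes dropped to 1279 without control replicate 3 and to 1547 without mimic replicate 3. It was 1938 (819 risen, 1119 fallen) without mimic replicate 1, the mimic array that differed most from the other mimic arrays, and 1801 (1023 risen, 778 fallen) without mimic replicate 2, so the balance of rises and falls depended on the arrays used. No call of the 2480 changed sign in any of these fits, which for genes whose groups do not overlap is fixed in advance.

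Among the 12 genes with the largest rises were genes of the cell surface, of lipid metabolism and of detoxification. The log2 value of Enpp2 (transcript cluster 10428619) was 10.12 ± 0.0787 with the mimic and 7.25 ± 0.221 with the control (SD, n = 3), a log2 fold change of 2.87 ± 0.10 (SE; limma adjusted p = 1.1e-06). In the authors' deposited table all 28 of its 28 exon-level probe sets were higher with p under 0.05. Ly6a, which encodes the surface protein known as Sca-1, rose 4.14-fold, from 9.51 ± 0.0977 to 11.56 ± 0.0598, and its relative Ly6c1 rose 3.97-fold, from 7.52 ± 0.0708 to 9.51 ± 0.0577 (SD, n = 3). Another member of this protein family, Lypd2, rose 2.30-fold. Gsta1, a glutathione S-transferase, rose 3.66-fold, and Aldh3a1, an aldehyde dehydrogenase, 2.14-fold. The remaining rises of this kind were Hephl1, a copper-dependent ferroxidase (2.72-fold), Tnfrsf9, a receptor of the tumour necrosis factor receptor family (2.50-fold), Car3, a carbonic anhydrase (2.46-fold), Tspan18, a tetraspanin (2.46-fold), Spa17 (2.21-fold) and Sptssb, a small subunit of serine palmitoyltransferase (2.15-fold). Their limma adjusted p ranged up to 0.0019, that of Sptssb. Ly6a, Ly6c1 and Gsta1 have near-identical relatives in the genome, so their probe sets may read more than 1 gene and their values are uncertain in that respect.

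The 12 largest falls included interferon-induced genes and genes of the extracellular matrix and its turnover. Ifit1 (transcript cluster 10462623) went from 9.64 ± 0.076 to 7.88 ± 0.144, a log2 fold change of -1.76 ± 0.08 (SE; limma adjusted p = 7.6e-06), and Ifit3 had a log2 fold change of -1.40. Mmp13, a collagenase, went from 10.33 ± 0.109 to 8.62 ± 0.152, and Mmp3, stromelysin, had a log2 fold change of -1.35. Has2, a synthase of hyaluronan, went from 9.70 ± 0.188 to 8.14 ± 0.0679, and Mfap5, a microfibril protein, had a log2 fold change of -1.45. Edn1, the precursor of the vasoconstrictor peptide endothelin, had a log2 fold change of -1.47. Upk3b, a uroplakin made by mesothelial cells, went from 11.48 ± 0.0162 to 10.08 ± 0.0875 (SD, n = 3), and all 10 of its 10 probe sets in the authors' deposited table were lower with p under 0.05. Log2 fold changes of -1.55 for the histone gene H2ac6, -1.52 for the adenylate kinase gene Ak4, -1.44 for Fgl1 and -1.37 for Rtn1 complete this set. The value of H2ac6 may be shared with other histone genes of like sequence, and Ak4 was read by a single probe set, while a second transcript cluster under this symbol had a log2 fold change of -1.16.

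**Figure D1:**
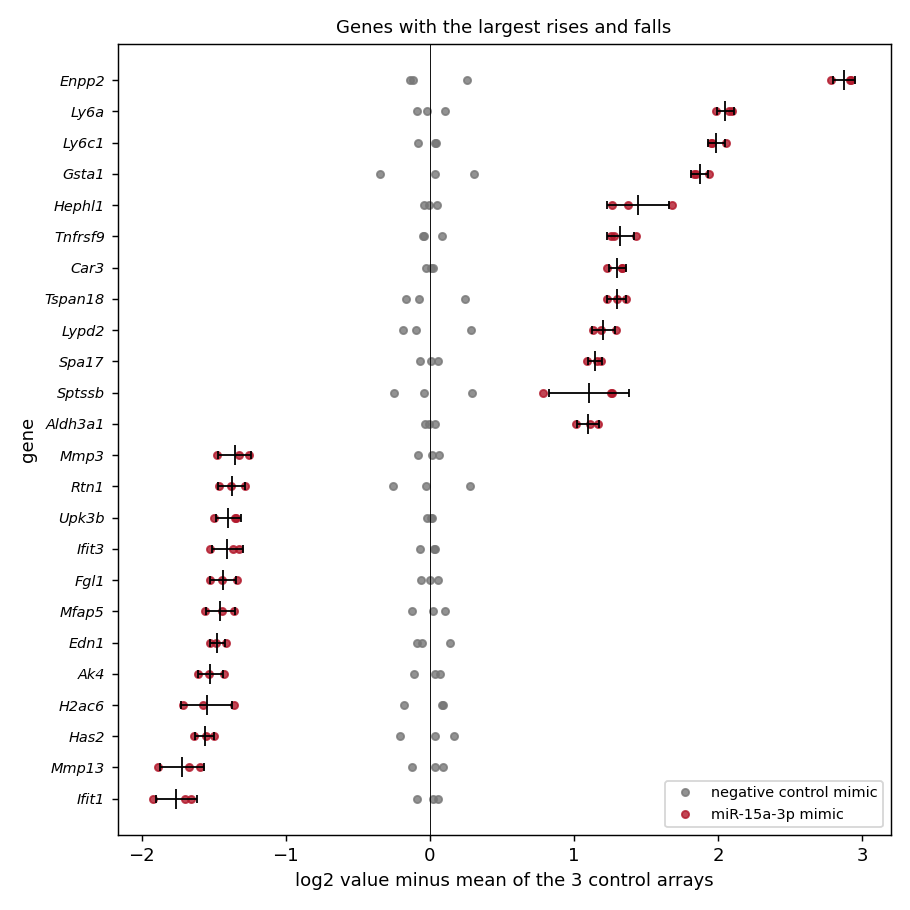
Log2 value of each array minus the mean of the 3 control arrays (x axis) for the 12 genes with the largest rises and the 12 with the largest falls (y axis), with 1 point per array, grey for the negative control mimic and red for the miR-15a-3p mimic, and a black mark with bars for the mimic mean ± SD. The rule for these genes required the 3 mimic arrays to lie apart from the 3 control arrays. Mean differences run from 2.87 for Enpp2 to -1.76 for Ifit1.

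Most genes on the list fixed for the interferon response were lower in the cells given the miR-15a-3p mimic. The list does not hold every gene induced by interferon, and Ifi30, given below, lies outside it and rose. Of the 35 measured members of the list fixed for this response, 26 fell and 2 rose, the same numbers when p was adjusted over the list alone, and the median log2 fold change was -0.47. Beside Ifit1 and Ifit3, Oasl2, a relative of the antiviral oligoadenylate synthetases, went from 10.12 ± 0.0484 to 9.24 ± 0.0491 (SD, n = 3; limma adjusted p = 7.3e-05). Usp18, which removes ISG15 from proteins and dampens interferon signalling, went from 8.92 ± 0.0183 to 8.11 ± 0.0503. The 2 that rose, named after their values were seen, were the chemokine gene Ccl5 (log2 fold change 0.47) and the peptide transporter gene Tap1 (0.32), and in most fits without 1 array a single member rose. The list's camera test gave an adjusted p of 2.8e-21 with the preset correlation, and the adjusted p = 0.12 with an estimated correlation did not pass. Beside this and the groups that follow, 2 of 12 granulosa cell markers were lower in the same cells. Of 20 fibroblast and mesothelial markers 3 fell (Upk3b, Lrrn4 and Wt1) and 3 others rose, and that list was not called (camera adjusted p = 0.90).

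Genes of cholesterol synthesis fell together. Of the 25 members of the sterol list, 22 fell and none rose (0 of 25), with or without adjustment over the list alone, and the median log2 fold change was -0.43. Lss, which closes the ring of lanosterol, went from 9.94 ± 0.111 to 8.86 ± 0.12 (SD, n = 3), a log2 fold change of -1.08 ± 0.08 (SE; limma adjusted p = 0.00011), and 20 of its 22 probe sets in the authors' deposited table were lower with p under 0.05. Mvd and Pmvk, enzymes of the mevalonate pathway, had log2 fold changes of -0.67 and -0.65. The camera test gave an adjusted p of 2.8e-21 with the preset correlation and an adjusted p = 0.12 with an estimated correlation.

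Genes of DNA replication, of mitosis and of histone supply were lower as well, each in part of its list. Of 29 genes of the G1/S phase and DNA replication, 11 fell and 0 rose (13 fell when adjusted over the list alone; median log2 fold change -0.16). Rrm1, the large subunit of ribonucleotide reductase, went from 11.13 ± 0.0678 to 10.28 ± 0.00751 (SD, n = 3), and Pole, a catalytic DNA polymerase subunit, and Lig1, a DNA ligase, had log2 fold changes of -0.57 and -0.45. Of 29 genes of the G2/M phase and mitosis, 12 fell and 1 rose (19 and 1 when adjusted over the list alone; median -0.25). Ccnb2, a mitotic cyclin, went from 9.91 ± 0.0296 to 9.06 ± 0.11 (SD, n = 3), while Ccnb1, named after its value was seen, rose with a log2 fold change of 0.42, a rise not called without mimic replicate 1, mimic replicate 3 or control replicate 3. Hmmr, Nuf2 and Ect2, which act at the spindle, the kinetochore and in cytokinesis, had log2 fold changes of -0.76, -0.51 and -0.43. Of 23 replication-dependent histone genes, 9 fell and 0 rose (16 fell when adjusted over the list alone; median -0.23), with H2ac4 at a log2 fold change of -0.90 and H1f3 at -0.46, both of families with near-identical members. H2ac4 was dim, at 5.84 in the control and 4.94 with the mimic, and was read by 1 probe set.

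The adjusted camera p was 1.3e-08 for the G1/S list, 3.7e-11 for the G2/M list and 8.3e-10 for the histones, and with an estimated correlation the adjusted p = 0.32, 0.46 and 0.25. With 1 array left out, the number of fallen members lay between 6 and 11 for the G1/S list (6 without control replicate 2 or control replicate 3, 7 without mimic replicate 2) and between 3 and 11 for the histones (3 without mimic replicate 2 or control replicate 3, 4 without mimic replicate 3, 5 without control replicate 1 or 2).

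Genes of glycolysis and of the response to low oxygen were lower in part. Of 28 members, 11 fell and 0 rose (12 fell when adjusted over the list alone), and the median log2 fold change was -0.17. Tpi1, a glycolytic enzyme, had a log2 fold change of -0.92 ± 0.06 (SE; limma adjusted p = 5e-05), and Pgk1, another, went from 12.69 ± 0.00838 to 12.19 ± 0.0232 (SD, n = 3). Aldoc, an aldolase, had a log2 fold change of -0.71, and Bnip3, a mitophagy receptor induced by low oxygen, of -0.95. Tpi1, Pgk1 and Bnip3 each have further transcript clusters under the same symbol, whose log2 fold changes were -0.86, -0.50 and -0.89. For Pgk1, 1 of these (10498313) gave the same mean and fold change as the cluster used and is no separate reading. The Bnip3 cluster used was read by 1 probe set and the further one by 6. The adjusted camera p was 2.5e-08 with the preset correlation and the adjusted p = 0.46 with an estimated correlation.

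Smaller shifts in the same direction were called for lists of extracellular matrix, granulosa cell and lysosome genes. Of 34 matrix genes 5 fell and 1 rose (the same over the list alone), among them Dcn, decorin, with a log2 fold change of -0.30, Mmp3, given above, Tnc, tenascin, at -0.31, Lox and Lum, while the fibrillin gene Fbn1 rose (0.40), although a dimmer transcript cluster under its symbol had -0.05 (adjusted p = 0.70) and the call was lost in the mean of its clusters. Of 12 granulosa cell markers 2 fell (2 over the list alone): Inhbb, which encodes an activin and inhibin subunit, at -0.63, and Fst, follistatin, at -0.50, while Foxl2 and Cyp19a1 did not pass the test (limma adjusted p = 0.098 and 0.36). Of 30 genes of the lysosome and autophagy 5 fell and 1 rose (6 and 1 over the list alone), with Psap, the precursor of the saposins, at -0.76, Grn at -0.25, Map1lc3a, Gabarapl1 and Asah1 among the former and Mcoln1 as the latter. In the granulosa list, 2 of the 12 markers had a mean log2 value at or above the median of all genes, so most of it was dim. The list medians were -0.09, -0.09 and -0.07. The adjusted camera p was 0.032, 0.039 and 0.026, and with an estimated correlation the adjusted p = 0.63, 0.64 and 0.87. These calls were lost without single arrays: the matrix list without mimic replicate 2 (adjusted p = 0.11), the granulosa list without mimic replicate 3 (0.10) or control replicate 1 (0.21), and the lysosome list without mimic replicate 2 (0.13) or control replicate 2 (0.13). With 1 array left out, 1 to 4 matrix genes and 1 to 4 lysosome genes fell (1 matrix gene without control replicate 3, 2 without control replicate 2, mimic replicate 2 or mimic replicate 3, and 1 or 2 lysosome genes without any array but mimic replicate 1). The call of Dcn was lost without control replicate 3, those of Tnc without mimic or control replicate 2 or 3, and those of Grn, Map1lc3a and Gabarapl1 without most single arrays, and Mcoln1 did not pass with any 1 array left out.

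**Figure D2:**
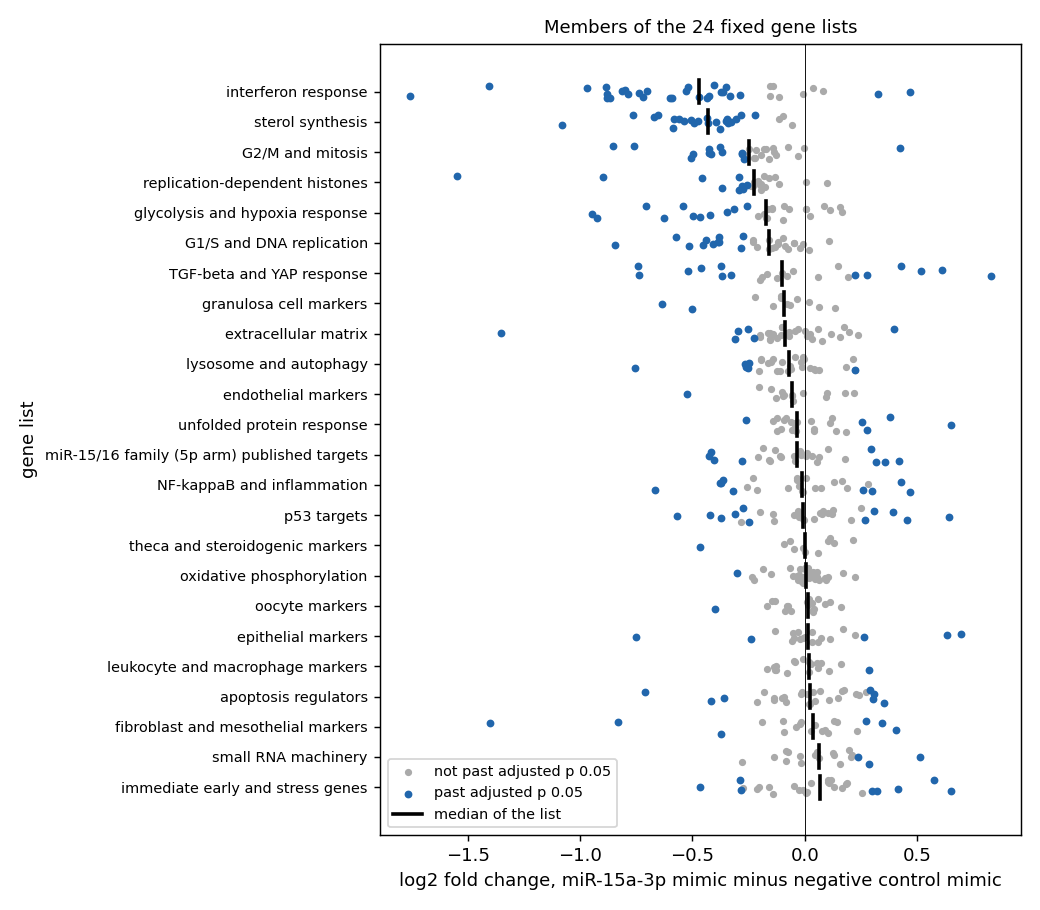
Log2 fold change, miR-15a-3p mimic minus negative control mimic (x axis), of the measured members of the 24 gene lists (y axis), with 1 point per gene, blue where the gene passed a limma adjusted p of 0.05 and grey where it did not, and a black bar at the list's median. The interferon and sterol lists lie furthest to the left, with medians of -0.47 and -0.43.

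Genes of other signalling and stress responses changed in both directions, and their lists were not called. Of all 21156 genes, 1286 rose and 1194 fell, and 2034 of these 2480 lay at or above the median of gene means. The counts below, and those of the matrix and lysosome lists above, are to be read against this share. Several may be no higher than that of other bright genes, which was not tested. Of 25 NF-kappaB and inflammation genes 4 rose and 5 fell (4 and 7 over the list alone): the chemokine genes Ccl2 (log2 fold change 0.47) and Ccl7, the inhibitor gene Nfkbia (0.43) and Vcam1 rose, and Cxcl5 (-0.67), Ptgs2 (-0.37), the gene of an inducible cyclooxygenase, Tnfaip3, Csf1 and Lif fell, with 2 rises without mimic replicate 3 and 2 falls without control replicate 3. Of 30 targets of p53, 5 rose and 6 fell (6 and 8 over the list alone): Trp53inp1 (0.64), Sesn3 (0.45), Ddit4, Polk and Rrm2b rose, while Cdkn1a (-0.57), the gene of the p21 inhibitor of cyclin-dependent kinases, and Ccng1 (-0.42) were among those that fell. With 1 array left out, 2 of the p53 targets rose without mimic replicate 1 and 3 without mimic replicate 2, mimic replicate 3, control replicate 1 or control replicate 3. In the same fits 2 fell without control replicate 3 and 3 without control replicate 2, mimic replicate 2 or mimic replicate 3. Of 23 genes of the TGF-beta and YAP response 6 rose and 7 fell (7 and 10 over the list alone), with Tgfbi (0.83) and the receptor gene Tgfbr1 (0.61) among the former and Cnn1 (-0.74) and Bmp4 (-0.52) among the latter. Of 24 genes of the unfolded protein response 4 rose, the transcription factor genes Atf3 (0.65) and Ddit3, Trib3 and Canx, and 1, Pdia6, fell (the same over the list alone); the calls of Canx and Pdia6 were lost without mimic or control replicate 2 or 3, and 2 genes rose without mimic replicate 3, control replicate 2 or control replicate 3. Of 28 immediate early and stress genes 5 rose, Klf4 (0.41), Nqo1 (0.57), Myc, Txnrd1 and again Atf3, and 3 fell, Srxn1 (-0.46), Dusp1 and Hmox1, with 6 and 6 over the list alone, and 1 fell without mimic replicate 2, mimic replicate 3 or control replicate 3. Of 29 regulators of apoptosis 4 rose (among them Bmf, Bcl2l11 and Xiap) and 3 fell (Bcl2l1, Casp4 and Casp12), with 4 and 4 over the list alone, and 0 rose without mimic replicate 1, mimic replicate 3 or control replicate 3 and 2 without control replicate 1. The survival gene Bcl2l1 had a log2 fold change of -0.71 ± 0.06 (SE; limma adjusted p = 0.00019), with 11 of its 17 probe sets lower with p under 0.05 in the authors' deposited table. Of 30 genes of oxidative phosphorylation 1, Cyc1, fell (0 over the list alone), and this call was lost with any array but mimic replicate 1 left out. The adjusted camera p of these 7 lists lay between 0.28 and 0.90.

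Markers of other cell types of the ovary moved in few members. Of 20 epithelial markers the keratin genes Krt8 (0.69), Krt18 (0.26) and Krt19 (0.63) rose and Krt7 (-0.75) and Muc1 (-0.24) fell. Of 20 fibroblast and mesothelial markers Pdgfra (0.34), Snai2 (0.27) and Krt14 (0.41) rose, and Upk3b (-1.40), Lrrn4 (-0.83) and Wt1 (-0.37) fell. Of 11 theca and steroidogenic markers Scarb1 (-0.47), a lipoprotein receptor, fell, of 19 oocyte markers Ddx4 (-0.40), of 15 endothelial markers Tek (-0.52), and of 19 leukocyte markers Cd74 (0.28) rose, a call lost without mimic replicate 3, control replicate 2 or control replicate 3. Over each list alone these counts were the same, save for 1 theca marker, Lhcgr, that rose. Ddx4 and Lhcgr were dim, with mean log2 values of 4.91 and 4.52 in the control. Most members of these lists were dim too. A mean log2 value at or above the median of all genes was reached by 2 of the 19 oocyte and 3 of the 19 leukocyte markers. It was reached by 1 of the 15 endothelial and 3 of the 11 theca markers. A lack of change in these 4 lists therefore cannot be read. Of the fibroblast and mesothelial markers, 1 rose when any 1 mimic array or control replicate 3 was left out. The call of Krt18 was lost with any 1 array left out, and that of Muc1 with any array but control replicate 1 left out. The adjusted camera p of these 6 lists lay between 0.38 and 0.90. The sign of the median differed from that of the mean or of the test in the p53, unfolded protein, theca, oocyte, leukocyte, fibroblast and oxidative phosphorylation lists, none of which was called.

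For the microRNA itself, the probe set of the precursor gene Mir15a read 8.23 ± 0.0827 with the mimic and 7.56 ± 0.233 with the control (SD, n = 3), a log2 fold change of 0.67 ± 0.11 (SE; limma adjusted p = 0.0039), and it does not tell the arms of the precursor apart. Its neighbour Mir16-1 had a log2 fold change of 0.32 (adjusted p = 0.16), and the host transcript Dleu2 one of 0.08 (adjusted p = 0.69). Both were dim and read by 1 probe set each, Mir16-1 at 5.27 with the mimic and 4.95 with the control and Dleu2 at 3.54 and 3.46. A lack of change in them therefore cannot be read. Of 19 genes of the small RNA machinery 3 rose and 0 fell (3 and 1 over the list alone): Dcp2 (0.51), a decapping enzyme, and Tnrc6a (0.29) and Tnrc6b (0.23), partners of Argonaute. The calls of Tnrc6a and Tnrc6b were lost without mimic replicate 1, mimic replicate 3, control replicate 1 or control replicate 3. That of Tnrc6b was also lost without control replicate 2 and under median centring. Ago2 and Dicer1 did not pass (log2 fold change 0.19 and 0.13, limma adjusted p = 0.16 and 0.29). Of 26 published targets of the opposite, 5p, arm of the miR-15/16 family 4 rose and 4 fell (4 and 5 over the list alone), with falls of Ccnd3 (-0.42), a D-type cyclin, its partner Cdk6 (-0.43), Arl2 (-0.41) and Kif23, and rises of the activin receptor gene Acvr2a (0.42), Ccnd1, Wee1 and Fgf2. The rises among these targets numbered 1 without control replicate 3 and 2 without mimic replicate 1 or mimic replicate 3. The adjusted camera p was 0.19 for the machinery and 0.42 for these targets.

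The fallen genes overlapped with the authors' own selection. The authors' deposited list holds 1768 exon-level probe sets, which carry the symbols of 865 genes tested here, and each has p under 0.05 and a fall of 2-fold or more in the authors' deposited table. Of these 865 genes, 413 were among the 1194 that fell in the limma fit, against 48.8 for independent lists (Fisher's exact test, p = 5.1e-299), and 2, Ryr2 (log2 fold change 0.24) and Tmem63b (0.27), were among those that rose, against 52.6. In the per-array gene values 740 of the 865 were lower with the mimic, 174 by at least 1.5-fold and 26 by at least 2-fold. Both lists come from the same arrays, so the overlap compares analyses and is no independent evidence of the falls.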

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

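The tests on mimic replicate 1 below were chosen after the result they bear on was seen.

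Values outside the tested genes also differed, for cluster IDs without a single gene name. Of 11407 clusters with no symbol or several, 36 passed a limma adjusted p of 0.05 within this set, 15 higher and 21 lower with the mimic, and 1578 had an unadjusted p under 0.05. What these clusters read, including whether any are array controls, was not examined, and they are not counted as further changed transcripts. Clusters 10429573, 10587331 and 10587339, which were higher, have IDs close to those of Ly6c1 (10429568) and Gsta1 (10587323), given above.

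The authors' deposited list holds falls alone, while 1375 exon-level probe sets of the authors' deposited table were at least 2-fold higher with p under 0.05, against 1768 that were lower by the same measure. Both counts rest on unadjusted p-values, and with those of 241419 probe sets they include calls made by chance.

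The authors' comparison appears to set mimic replicate 1 apart, as its ratios were matched best with that array left out. A response weaker by over 0.1 in slope is argued against, though a smaller shortfall is not: over the 300 genes that moved most in the other arrays, its fold changes had a slope of 0.914 on those of the other mimic arrays, taken against different controls, and those of replicates 2 and 3 had 0.934 and 0.955 (shortfall from the lower of these 0.0202, SD 0.0139 over the 3 controls). More noise in it remains open: its root mean square difference from the other mimic arrays was at least 1.104 times that between those, just above the bound of 1.1 set for this test. The difference between control replicates 1 and 2 was greater still (0.189, against 0.168 and 0.159 for the pairs with mimic replicate 1). No biological explanation was tested. Without this array 1938 genes changed, 819 up and 1119 down, and 1733 of the 2480 calls were kept.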

How the results depend on the processing

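Each alternative was chosen before the data were examined. The signs of the 2480 calls held wherever they were retested, and none of the 119 named genes changed direction (0 in 15 alternatives). Under the filters on dim genes, the replicate block, the trended prior and all clusters fitted, the fold changes are those of the main fit. Their signs could not change there. Leaving out 1 array cannot turn the sign of a gene whose groups do not overlap either. Of the 97 named genes past the threshold, 16 lost the call somewhere, 15 of them with 1 array left out. With 1 array left out, 1279 to 2060 genes changed (674 to 1112 risen, 605 to 1121 fallen), fewer arrays being tested, and the lowest counts came without control replicate 3. Array weights, whose estimation stopped before it converged and gave control replicate 3 a weight of 6.76, called 5707 genes (2832 risen, 2875 fallen). A required change of 1.5-fold left 380 (176 risen, 204 fallen), with p adjusted or not. The other counts lay between 1727 and 3448. The replicate number as a block gave that 1727 (884 risen, 843 fallen), with 1693 of the calls kept and no list call changed. The arrays share only a number: deviations of same-numbered arrays correlated at -0.05, -0.28 and 0.04, and no array correlated best with its own number. With an estimated correlation the adjusted p was 0.121 for the interferon and sterol lists, 0.317 for G1/S, 0.459 for G2/M and for glycolysis, 0.252 for histones, 0.634 for matrix, 0.636 for granulosa and 0.874 for lysosome genes. This setting allows for genes of a list varying together. Fry gave 0.0624 for matrix, 0.0904 for granulosa and 0.105 for lysosome genes, and the opposite direction for leukocyte markers (0.929) and apoptosis (0.868). Under the filter at the median, matrix and lysosome had 0.0990 and 0.0570. Under the filter at 6, matrix, granulosa and lysosome had 0.122, 0.128 and 0.0641, and theca (0.864), oocyte (0.864) and leukocyte markers (0.862) turned. Under quantile normalization matrix and lysosome had 0.106 and 0.0656, and theca (0.991), fibroblast (0.930) and oxidative phosphorylation lists (0.930) turned. Granulosa markers had 0.0630 with the trended prior and 0.129 with array weights, where apoptosis turned (0.944). With 1 array left out, the adjusted p ranged from 0.0131 to 0.110 for matrix, 0.0245 to 0.211 for granulosa and 0.00407 to 0.126 for lysosome genes. Over the same fits, lists that turned in some fit, none called in any, ranged from 0.797 to 0.972 (apoptosis), 0.767 to 0.950 (p53), 0.888 to 0.984 (theca), 0.384 to 0.905 (oocyte), 0.577 to 0.967 (leukocyte) and 0.437 to 0.844 (oxidative phosphorylation). The calls on the interferon, sterol, G1/S, G2/M, histone and glycolysis lists held in the 15 alternatives run for lists except the estimated correlation, and the lists were not run under other ways of handling several clusters of a gene or other thresholds. Where no cause is named, the cause was not tested. With the authors' list 413 fallen genes were shared, 460 at an adjusted p under 0.1, and 174 when the list was cut to the 174 genes with a 1.5-fold fall in the per-array values, a selection that fixes this outcome, since all 204 genes with such a fall were called. The seed-site test and the authors' deposited table as a source of values were not run. The values carry no detection call, so changes of dim genes cannot be set against background.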

Other observations

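Except for the count of splits and the Wnt test, the tests in this part were chosen after the result they bear on was seen, and the genes outside the fixed rule were picked from their values.

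Some changes outside the fixed lists stood out by size. Itga1, the collagen-binding integrin alpha subunit, had a log2 fold change of -1.35, the growth factor receptor gene Fgfr2 one of -1.05 and the ephrin receptor gene Epha4 one of -1.09. Ifi30, a lysosomal thiol reductase induced by interferon, rose (0.78), the opposite of most of the interferon list. The cystine transporter gene Slc7a11 rose (0.77). The paired genes Sectm1a (0.84) and Sectm1b (0.94) rose together, as did the tetraspanin genes Tspan18 and Tspan8 (0.96). No enrichment was tested for these genes.

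Of the 10 ways to divide the 6 arrays into groups of 3, the real one called 2480 genes, as many as 1 split, itself, and the highest of the others called 0. The real division called 9 lists, again reached by 1 split, itself, and the highest other called 8. Each other split sets 2 arrays of one group and 1 of the other against the rest, so part of the real difference remains in it. That part is the same in each, yet these splits called from 0 to 8 lists, with 0 genes called. The number of lists called thus also depended on variation between arrays. Small camera p-values at the preset correlation may therefore overstate the evidence for a list. With 10 splits the share cannot go under 0.1, so whether chance can be excluded is not settled by this count.

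The falls in the interferon list form a broad shift, 26 of 35 members. A single array carrying it is argued against, since with any 1 array left out the median log2 fold change stayed at -0.469 or lower. A remaining difference in array scale is argued against too: the array medians lay between 6.94 and 7.01, and the list's median was -0.473 or lower after quantile normalization or centring. Since the deposited values were already normalized, these steps could move the list little and do not test the authors' own scaling. What stays open is whether the microRNA mimic lowered these genes or the negative control mimic raised them, as transfected double-stranded RNA may do: 0 of the 6 arrays came from untransfected cells, so these cannot be told apart.

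The risen genes Ly6a, Ly6c1, Ly6e (0.90) and Lypd2 lie among 20 consecutive measured genes of chromosome 15 in the order of assembly GRCm38.p6. A shift of the whole segment is not settled: all 20 genes had a median of 0.14 (SD 0.644), and of the other 16 genes Them6 (0.47) and Lynx1 (0.42) rose too and 0 fell. The SD includes the 4 risen genes, which widens it, so it cannot decide the question. The rise was not shared by every gene, as Slurp2 (-0.02), Ly6k (-0.05) and Ly6m (-0.04), which lie between the risen genes, did not pass. Chance remains open as well: in 0.0739 of 1000 shuffles of the fold changes some run of 20 neighbours held as many genes risen by 1.5-fold, and runs on chromosome 14 also held 4. Cross-reading between relatives cannot be told apart from separate rises, since 0 probe sequences were used here. A shared response of this gene family is a hypothesis that these arrays leave untested.

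The Wnt targets Axin2 (0.82), Lgr5 (0.73) and Lef1 (0.57) rose, and Nkd1 (0.32) did not pass (limma adjusted p = 0.059), which raised the hypothesis of a general rise of Wnt targets. It was tested on 16 other targets whose values had not been seen: Tcf7 (0.69) and Fzd7 (0.33) rose and 0 fell, but camera gave p = 0.406 (0.692 with an estimated correlation). The test neither bears out nor excludes a wider rise, since the 6 of these targets with a mean log2 of at least 7 had a median of 0.15 (SD 0.277).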
